A study of Mus musculus with 2 samples.

How the data were processed

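Single cells of optic nerves from Nf1-OPG mice were measured with the 10x Genomics 5′ version 2 chemistry in 1 vancomycin and 1 control library. The control library carries the treatment label control, and the series design names PBS as the alternative to vancomycin, given from 6 to 12 weeks of age. Each library came from a pool of 10 mice harvested at 12 weeks, per the labels' protocols. The protocols describe the optic nerves, which went through enzymatic dissociation and removal of debris and myelin, and also the meningeal dura, whose cells were stained for dead cells and sorted. Both libraries have optic nerve as their tissue label. The title of the control library carries a further tag (ON) that the title of the vancomycin library lacks, and the meaning of the tag was not assumed.

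The deposited values are raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 7.2.0 for the vancomycin library and 6.0.1 for the control library, per the file headers. The genome build was mm10 and Partek was also used, per the submitters' processing notes. Whether reads in introns were counted, and how the barcodes were called as cells, is not given in the sources used here. The smallest UMI count of a barcode was 500 in both libraries.

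All values were computed from these counts with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and with R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 for scaling factors only. Gene positions came from the GENCODE M21 annotation of GRCm38, the assembly of mm10, in which 32235 of the 32285 gene identifiers (99.85%) were found. Cells kept had at least 500 UMIs, at least 200 genes and at most 20% of UMIs from mitochondrially encoded genes. This left out 870 vancomycin barcodes (5.24%) and 164 control barcodes (3.84%), and the medians of mitochondrial UMIs among kept cells were 1.565% and 1.555%. Doublets were called with Scrublet on each library alone. It marked 522 vancomycin cells (3.32%, threshold 0.200) and 0 control cells (threshold 0.511), so the call has not worked in the control, where 48 cells (1.17%) lay above a common threshold of 0.2.

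Cells of both libraries were clustered together without integration, from counts scaled to 10000 per cell, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0. A cluster took the name of the class, written as X-like, whose markers had the highest mean log2 fold over all other cells, out of 30 fixed marker sets. A marker was detected in at least 0.1 of the cluster's cells at 2 times the level of other cells, and at least 3 were needed, with the top 10 genes by fold inspected. A cluster with at least 2 hormone or granule genes among its top 20 stayed unnamed, a rule set after the clusters were seen. A class was compared where it held at least 50 cells in each library (20 for T cells), which gave 9 classes. CD8 and CD4 T cells were called from single UMIs, unthinned and with each cell thinned to 1000 UMIs.

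Within a class, UMIs were summed over cells and scaled to the total of the class (CPM), and the log2 ratio was taken after adding 10 CPM to both. Intervals for shares are exact binomial (Clopper-Pearson) and those for ratios exact conditional Poisson, at 95%. They cover counting error only, and no test was made. A level of 0 was given a floor of 3 counts, over the class in that library. Genes were named by a rule fixed in advance, from genes with at least 50 UMIs, at least 100 CPM in the higher library and an interval that left out 1. It took the 10 highest and 10 lowest ratios in T cell-like, microglia-like and fibroblast-like cells and 3 each way in the other classes. It left out families such as ribosomal, haemoglobin, immunoglobulin and T cell receptor variable genes and the markers of other classes. A set of 14 genes of the T cell, TGF-beta and Nf1 question was given wherever measured. The rule also took 2 members by level and 2 by ratio of every list. In T cell-like, microglia-like and fibroblast-like cells this was narrowed, by topic and after results were seen, to the lists treated as answering a comparison, and in the other classes to none. Values of some single genes are not reported here.

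The 29 gene lists covered CD8 identity and cytotoxicity, CD4 and regulatory, checkpoint, naive, tissue-resident and homing genes of T cells, T cell recruiting chemokines, the TGF-beta pathway, the optic glioma T cell to microglia axis, and homeostatic and disease-associated microglia. Others covered type I interferon, interferon gamma and MHC class I, MHC class II, NF-kappaB and cytokines, immediate early genes, heat shock, proliferation, RAS-MAPK output, glycolysis and hypoxia, oxidative phosphorylation and ribosomal proteins. The rest were myelin, cholesterol synthesis, reactive astrocytes, microbial metabolite sensing, the blood-brain barrier, sex-linked genes and mitochondrially encoded genes. A list was given where at least 5 members had at least 10 UMIs. The percentile of its median among 10000 random lists matched on mean CPM (25 bins) describes these libraries and is not evidence about the treatment. Members were counted as at least 2-fold different where the log2 ratio after adding 10 CPM was at least 1 in size and the interval also left out 1.

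The ratio intervals and list percentiles were tested on simulated counts with the depths of the T cell class. Of 13375 genes, 96.0% of the intervals held the true ratio. Of 50 genes set to each fold, the interval left out 1 in the right direction for 100.0% at 0.25, 88.0% at 0.5, 86.0% at 2 and 100.0% at 4. A list raised 1.5 times lay at percentile 100.0, and 0 of 20 unchanged lists lay outside the central 95%.

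Alternatives covered the filter on cells, doublets, clustering resolution, clustering each library alone, other denominators, other definitions of T and proliferating cells, thinning, equal weight per cell, edgeR TMM and DESeq2 size factors, the pseudocount and the filter on list members. Added after the data were seen were 1 doublet threshold for both libraries, log2 ratios less the median of the other classes, shares without oligodendrocyte-like cells, lists without genes different in every class that measured them, and random lists also matched on intronic length.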

Results

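Single-cell RNA was measured in optic nerve cells of Nf1-OPG mice, a mouse strain that lacks Nf1 in neuroglial progenitors and forms low-grade tumours of the optic nerve. One group received vancomycin, an antibiotic given here to act on gut bacteria, from 6 to 12 weeks of age. The other is labelled control, and the series design names saline (PBS) as the alternative to vancomycin. Nerves were taken at 12 weeks and those of 10 mice were pooled, so each group is 1 library. The vancomycin library held 16596 barcodes and 144451114 UMIs (unique molecular identifiers, 1 per captured RNA molecule), and the control library held 4272 barcodes and 25609899 UMIs. After filtering, 15204 vancomycin cells had a median of 6777 UMIs and 2468 genes, and 4108 control cells had a median of 4870.5 UMIs and 1912 genes. With 1 library per group there was no test and no replicate spread, and every interval below is a 95% interval for counting error only. A log2 ratio sets vancomycin over control after adding 10 CPM to both, so a positive value means a higher level in the vancomycin library. Genes counted as at least 2-fold higher or lower had a log2 ratio of at least 1 in size. The plain ratio, without the added CPM, can exceed 2-fold in low genes that are not counted. Genes called highest or lowest were ranked by log2 ratio within the naming rule. The series asks whether intestinal bacteria act on glioma through CD8 T cells, so the share of T cells, the share of CD8 cells among them and RNA levels within each cell class were compared.

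T cell-like and microglia-like cells made up a smaller part of the vancomycin library than of the control library. T cell-like cells were 23.4% of kept cells with vancomycin (3564 of 15204, interval 22.8 to 24.1) and 45.8% in the control (1883 of 4108, 44.3 to 47.4). Microglia-like cells, the resident macrophages of nervous tissue, were 9.44% (8.98 to 9.92) against 29.5% (28.1 to 30.9). Oligodendrocyte-like cells, which make myelin, were 25.7% of the vancomycin library (3904 cells, 24.98 to 26.4). The control had 0 of 4108, with an interval up to 0.0898%. Oligodendrocyte precursor-like cells were 7.69% (7.27 to 8.12) against 1.27% (0.947 to 1.66). Per the labels' protocols, myelin and debris were removed from the nerve suspensions and cells of the dura were sorted, steps that can set such shares.

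Among kept cells of immune classes, T cell-like cells were 40.8% of 8728 vancomycin cells and 50.6% of 3719 control cells. Per microglia-like cell there were 2.48 T cell-like cells with vancomycin (2.33 to 2.64) and 1.55 in the control (1.44 to 1.67). Antigen-presenting and antibody-secreting cells were more frequent in the vancomycin library. Dendritic cell-like cells were 8.91% against 2.92% (2.43 to 3.48), plasma cell-like cells 6.82% against 3.19% (2.67 to 3.77), B cell-like cells 2.43% against 0.755% (0.513 to 1.07) and border-associated macrophage-like cells 4.17% against 2.99% (2.49 to 3.56). Natural killer (NK) cell-like cells were 1.01% (0.854 to 1.18) against 2.99% (2.49 to 3.56) and innate lymphoid cell-like cells 0.303% (0.222 to 0.403) against 1.31% (0.989 to 1.71). Per T cell-like cell there were 0.291 plasma cell-like cells (0.271 to 0.312) against 0.0696 (0.0578 to 0.0831), and per microglia-like cell 0.944 dendritic cell-like cells (0.875 to 1.02) against 0.0989 (0.0813 to 0.119).

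The rarer classes also differed. Fibroblast-like cells were 2.02% (1.80 to 2.26) against 3.38% (2.85 to 3.98), astrocyte-like cells 1.39% (1.21 to 1.59) against 2.43% (1.98 to 2.95) and neutrophil-like cells 0.513% against 0.949% (0.676 to 1.30). Without oligodendrocyte-like cells in the total, the vancomycin shares were 2.72% (2.42 to 3.03), 1.88% (1.63 to 2.14) and 0.690% (0.546 to 0.861), intervals that overlapped those of the control. Erythroid cell-like cells were 1.08% against 0.170% (7 control cells), endothelial cell-like cells 0.691% against 0.0243% (1 control cell), pericyte-like cells 0.303% against 0.0487% (2 control cells) and plasmacytoid dendritic cell-like cells 0.362% against 0.0487% (2 control cells). A cycling cluster, a state and not a cell type, held 1.47% and 1.53%. A cluster led by hormone genes stayed unnamed and held 2.27% of vancomycin and 0.609% of control cells. A cluster held mostly by 1 library may reflect that library and not a cell type, and with each library clustered alone the control shares were 1.10% for dendritic cell-like, 2.12% for innate lymphoid cell-like, 0.438% for neutrophil-like and 4.11% for border-associated macrophage-like cells, the last beside 4.19% with vancomycin. Without a filter on cells, erythroid cell-like cells were 4.47% of the vancomycin library, and with doublets kept endothelial cell-like cells were 1.05%. The T cell-like cells lay mostly in clusters 8, 5, 21 and 13 with vancomycin and in clusters 13 and 4 in the control, microglia-like cells in clusters 11 and 6 against 0 and 11, and dendritic cell-like cells in clusters 16 and 7 against 16 and 18.

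**Figure D1:**
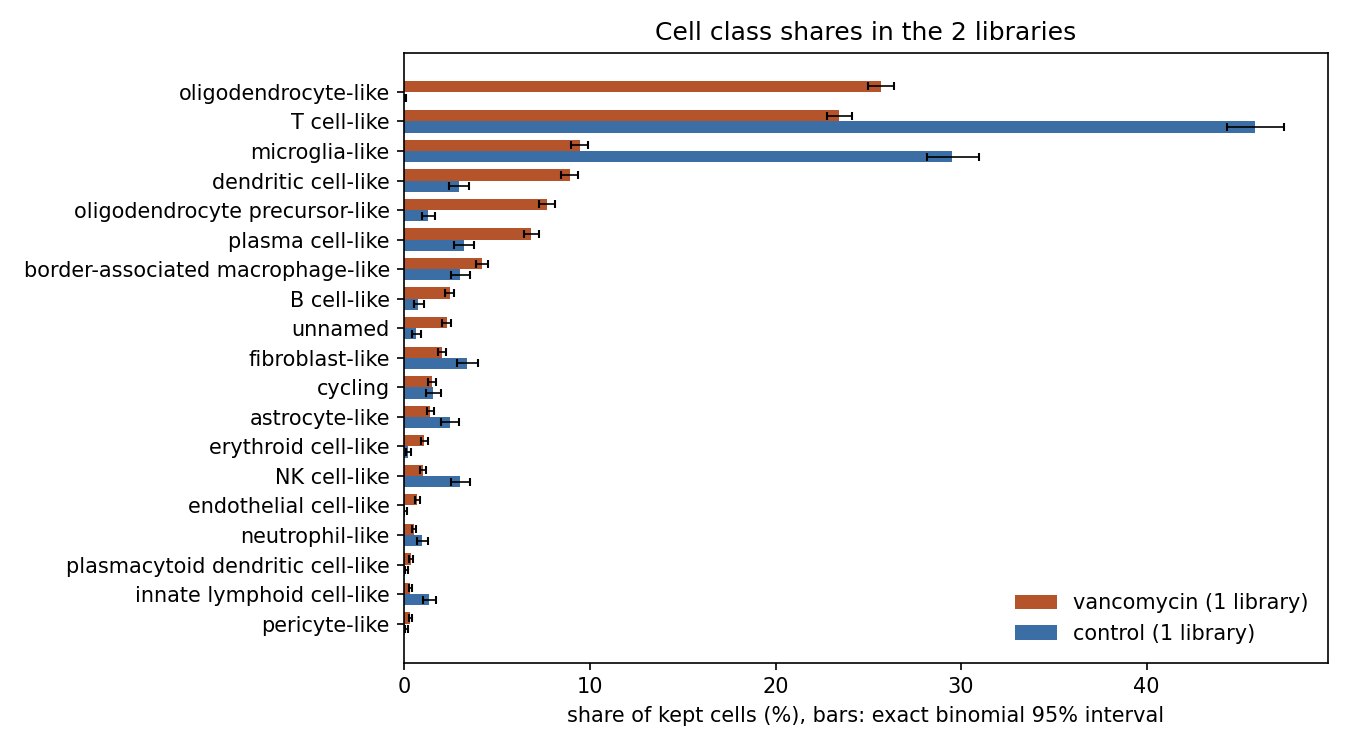
Share of kept cells (%, x axis) of each cell class in the vancomycin library (orange) and the control library (blue), 1 library each, with exact binomial 95% intervals as error bars. T cell-like cells reach 23.4% with vancomycin and 45.8% in the control, and oligodendrocyte-like cells 25.7% and 0%.

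CD8 T cells, the cytotoxic T cells named in the series title, were called from at least 1 UMI of Cd8a or Cd8b1, which encode the CD8 chains, and no UMI of Cd4. They were 37.9% of T cell-like cells with vancomycin (1349 of 3564, 36.3 to 39.5) and 47.3% in the control (891 of 1883, 45.0 to 49.6). Thinned to 1000 UMIs per cell, the shares were 34.8% (1223 of 3518, 33.2 to 36.4, 46 shallower cells left out) and 40.9% (723 of 1767, 38.6 to 43.3, 116 left out). The RNA level did not share this order for both chains. Cd8a (ENSMUSG00000053977, mm10 chromosome 6, 71373427 to 71379173) stood at 565 CPM (UMIs of the gene scaled to the total UMIs of the class) with vancomycin and 530.0 CPM in the control, a ratio of 1.06 (1.03 to 1.10). Cd8b1 (ENSMUSG00000053044, chromosome 6, 71322788 to 71337494) stood at 495 and 571 CPM, a ratio of 0.866 (0.837 to 0.896). The log2 ratio of Cd8a was 0.09, but -0.08 after thinning, -0.09 with every cell weighted equally and -0.23 less the other classes' median. Since Cd8a summed over cells went against the share and its direction turned with these settings, no order of CD8 T cells between the libraries is read from it.

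CD4 T cells, defined the other way round, were 33.3% (31.7 to 34.9) against 31.8% (29.7 to 33.9), and after thinning 15.2% (14.0 to 16.4) against 17.3% (15.5 to 19.1), a difference within the intervals. There were 1.14 CD8 per CD4 T cell with vancomycin (1.05 to 1.23) and 1.49 in the control (1.34 to 1.66), but 2.29 (2.07 to 2.54) and 2.37 (2.07 to 2.72) after thinning, so the gap was not detectable at equal depth. As background from free RNA, 2.02% of vancomycin and 2.14% of control microglia-like cells, which should lack CD8, met the same rule at median depths of 5168.5 and 4134 UMIs. The T cell-like cells had medians of 3877 and 4819 UMIs. After thinning the microglia-like shares were 0.916% and 1.08% (235 and 191 cells left out), and those for Cd4 were 0.333% and 0.587%.

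**Figure D2:**
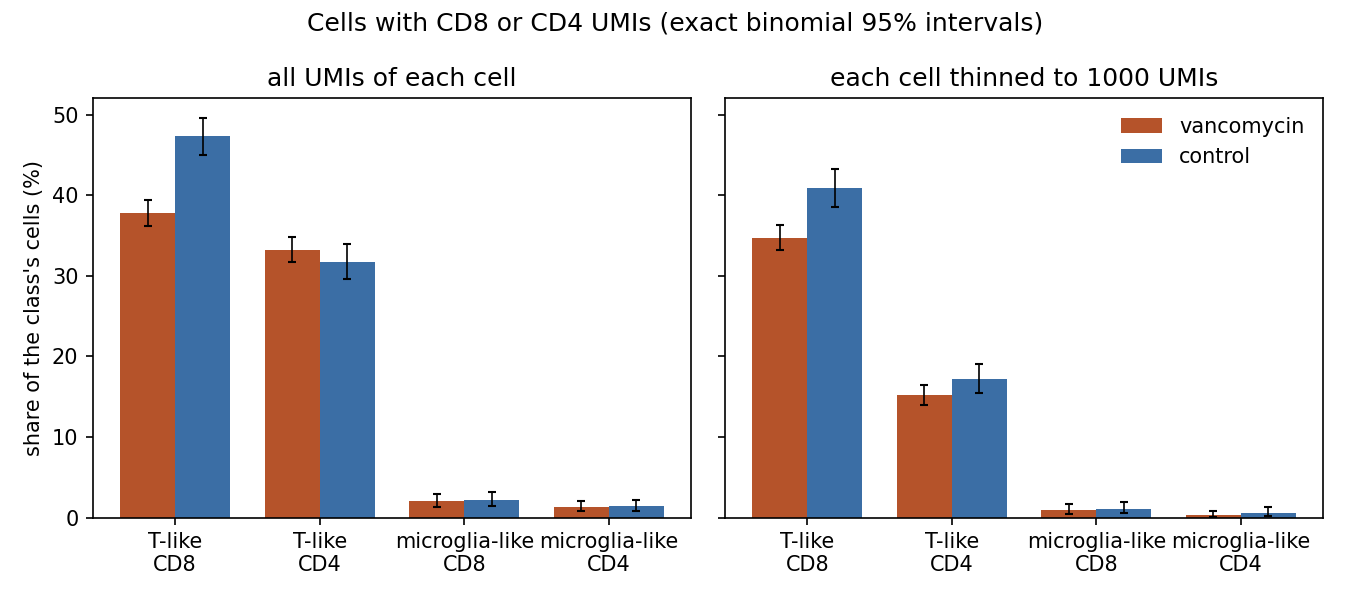
Share of cells (%, y axis) with CD8 or CD4 UMIs among T cell-like cells and, as background, microglia-like cells, for vancomycin (orange) and control (blue), with all UMIs (left) and thinned to 1000 UMIs per cell (right). Error bars are exact binomial 95% intervals, and the CD8 share of T cell-like cells is lower with vancomycin on both sides.

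Within T cell-like cells, chemokine RNA was higher and Tgfb1 RNA was lower in the vancomycin library. Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683), a chemokine that draws leukocytes, stood at 440.3 CPM against 105 CPM, a ratio of 4.18 (3.92 to 4.47). Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518), another such chemokine, stood at 4931 against 3730.3 CPM (ratio 1.32, 1.31 to 1.34), with a log2 ratio that turned to -1.26 less the other classes' median. Tgfb1 (ENSMUSG00000002603, chromosome 7, 25687002 to 25705077), which encodes transforming growth factor beta 1, stood at 189 against 589.8 CPM (ratio 0.321, 0.307 to 0.336). Tgfb1 was lower in microglia-like cells too (244 against 780.3 CPM). Of the 20 genes with the highest and lowest ratios in this class, 10 were at least 2-fold different in the same direction in every compared class that measured them, at least 5 of the 9.

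Genes of cytotoxic T cells went both ways. Of the 22 measured members of the CD8 identity and cytotoxicity list, 3 were at least 2-fold higher and 0 lower, with a median log2 ratio of -0.01 (percentile 56.45 of 10000 matched random lists) and a mean of 0.20, which differ in sign. Nkg7, a granule protein gene, stood at 1997 against 1234 CPM (log2 ratio 0.69, -0.27 less the other classes' median) and Ccl3 at 95.5 against 24.6 CPM (1.61). Interferon gamma (Ifng) had a log2 ratio of 0.67, granzyme B (Gzmb) 0.38 and granzyme K (Gzmk) -0.48. Of the 12 measured T cell recruiting chemokines, 3 were at least 2-fold higher and 0 lower, with a median of 0.40 (percentile 100). That median depended on the pseudocount, at 0.10 with 50 CPM and 0.77 with 1 CPM. The list of the optic glioma T cell to microglia axis had a median of 0.42 (percentile 99.96; 4 of 13 at least 2-fold higher, 0 lower), and shares Ccl4 and Ccl5 with the chemokines and the CD8 list, which share Ccl3 too. Its member Igf1r, a growth factor receptor gene, had a log2 ratio of 1.39, and Mdk, which encodes the growth factor midkine, stood at 4.73 against 1.03 CPM (ratio 4.58, 2.36 to 9.93).

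Checkpoint genes were mixed, with 3 of 15 at least 2-fold higher and 1 lower (median 0.18, percentile 92.48). Tox, a transcription factor gene of exhausted T cells, stood at 451 against 166 CPM (log2 ratio 1.39), Nr4a3, an activation-induced nuclear receptor gene, at 129 against 495 CPM (-1.86), Pdcd1, which encodes PD-1, at 0.33, Tigit at 0.18 and Ctla4 at 0.11. The CD4 and regulatory list had a median of 0.16 (percentile 88.19; 0 of 15 at least 2-fold in either direction), with Tnfrsf4 at 0.55, Il10 at 0.69, Ikzf2 at 0.63 and Cd4 at -0.26. Genes of naive and recirculating T cells lay lower without leaving the central 95% of random lists (median -0.29, -0.17 with a pseudocount of 50 CPM, percentile 3.14; 1 of 12 at least 2-fold lower, 0 higher). S1pr1, the receptor for exit from tissue, stood at 25.6 against 121 CPM (-1.88), Satb1 at -0.96 (plain ratio 0.478), Il7r at -0.22 and Tcf7 at -0.15, the last with the opposite sign after thinning. Homing and adhesion genes (median -0.19, -0.37 after thinning, percentile 2.76; 1 of 18 at least 2-fold higher, 0 lower) included Selplg at -0.68, Itgb1 at -0.95 and Alcam at 1.501. The tissue-resident list had a median of -0.21 (percentile 15.37; 1 of 11 at least 2-fold lower, 0 higher), with Rgs1 at -1.55, Bhlhe40 at -0.43 and Cd69 at 0.76. The log2 ratios of Bhlhe40 (0.56), Cd69 (-0.01), Il7r (0.53) and Cd4 (0.15) turned sign less the other classes' median.

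In the TGF-beta pathway list 3 of 22 measured members were at least 2-fold lower and 0 higher (median -0.02, percentile 21.54). Besides Tgfb1, Skil, a repressor of TGF-beta signalling that the pathway induces, had a log2 ratio of -1.42, the receptor gene Tgfbr2 -0.86 and Tgfbr1 0.46. Nf1, the gene lost in the tumour precursor cells, stood at 20.9 against 10.3 CPM in these T cells (ratio 2.02, 1.61 to 2.55). Its log2 ratio was 0.60, and -0.25 less the other classes' median. Genes of the respiratory chain and ATP synthase lay higher as a group (median 0.34, percentile 99.97; 0 of 26 at least 2-fold in either direction, 23 with an interval above 1), with Cox8a at 0.43 (-0.02 less the other classes' median), Atp5e at 0.21 (-0.13 so taken), Ndufb9 at 0.66 and Ndufs5 at 0.64. Cholesterol synthesis genes lay lower (median -0.30, percentile 0.09; 2 of 19 at least 2-fold lower, 0 higher), with Insig1 at -1.54, Cyp51 at -1.33 and Srebf2 at -0.65.

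Markers of other cells were also higher in these T cell-like cells. All 17 myelin genes were higher with an interval above 1 (median 0.85, percentile 100; 0.80 with 9 members at 0 set to 3 counts), and Mbp, a myelin protein gene, stood at 1047 against 120.0 CPM. Less the other classes' median, the log2 ratios of Mbp (-0.78), Cd74 (-0.06), H2-Ab1 (-0.61), H2-Eb1 (-0.25) and Ctss (-0.02) turned negative in this class. MHC class II genes of antigen-presenting cells had a median of 0.49 (percentile 99.97; 4 of 11 at least 2-fold higher, 0 lower), with Cd74 at 1.10, H2-Ab1 at 1.23, H2-Eb1 at 1.18 and Ctss at 0.24. With every cell weighted equally that median was 0.20, and with a pseudocount of 50 CPM also 0.20. Genes of disease-associated microglia had a median of 0.29 (percentile 99.78; 2 of 19 at least 2-fold higher, 0 lower), with Spp1 at 2.11, Apoe at 1.13, Ctsb at 0.39 and Ctsd at -0.16.

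Apart from the sex-linked list, the remaining lists lay inside the central 95% of random lists in T cell-like cells. Their medians were 0.00 for type I interferon, 0.11 for interferon gamma and MHC class I, 0.11 for NF-kappaB and inflammatory cytokines, -0.11 for immediate early genes, -0.06 for heat shock, 0.04 for proliferation (mean 0.00), 0.03 for RAS-MAPK output and 0.07 for glycolysis and hypoxia. They were 0.19 for ribosomal proteins (percentile 97.02), 0.06 for reactive astrocyte genes, 0.01 for microbial metabolite sensing (mean -0.10), -0.14 for the blood-brain barrier, -0.08 for homeostatic microglia and -0.07 for mitochondrially encoded genes. The sex-linked list, which reads the makeup of the pools, had a median of 0.94 and a percentile of 99.99.

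The genes with the highest ratios in T cell-like cells were mostly genes that stood higher in every class that measured them. Cmss1 (ENSMUSG00000022748, chromosome 16, 57302000 to 57606864, minus strand), which encodes a ribosomal small subunit homologue, stood at 8756 against 13.2 CPM (ratio 662, 557 to 794). Heph (ENSMUSG00000031209, chromosome X, 96455359 to 96574485), which encodes the ferroxidase hephaestin, stood at 1637 CPM against 0 control UMIs, at least 5285-fold higher when the control is set to 3 counts. Grik3, a kainate receptor gene, stood at 226 CPM against 0, at least 729-fold higher. The next by log2 ratio were Filip1l at 4.02, Mir142hg (host of a blood-cell microRNA) at 3.87, Gphn at 3.64, Cdk8 at 3.45, Camk1d at 2.65, Cnot6 at 2.52 and Nrgn at 1.99. At the low end stood Ftl1, which encodes ferritin light chain and has near-identical pseudogenes that can share its reads, at 120.1 against 968 CPM (ratio 0.124, 0.118 to 0.130). Ndufb4 at -2.57, Ramp3 at -2.27, Nsa2 at -2.03, Tinf2 at -1.91, S1pr1, Nr4a3, Dbf4 at -1.65, Vps37b at -1.64 and Lars2 at -1.59 followed. Less the median of the other compared classes, the log2 ratios of Cmss1 (-0.09), Grik3 (-0.68), Cdk8 (-0.45), Camk1d (-0.43) and Ftl1 (0.32) turned sign.

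**Figure D3:**
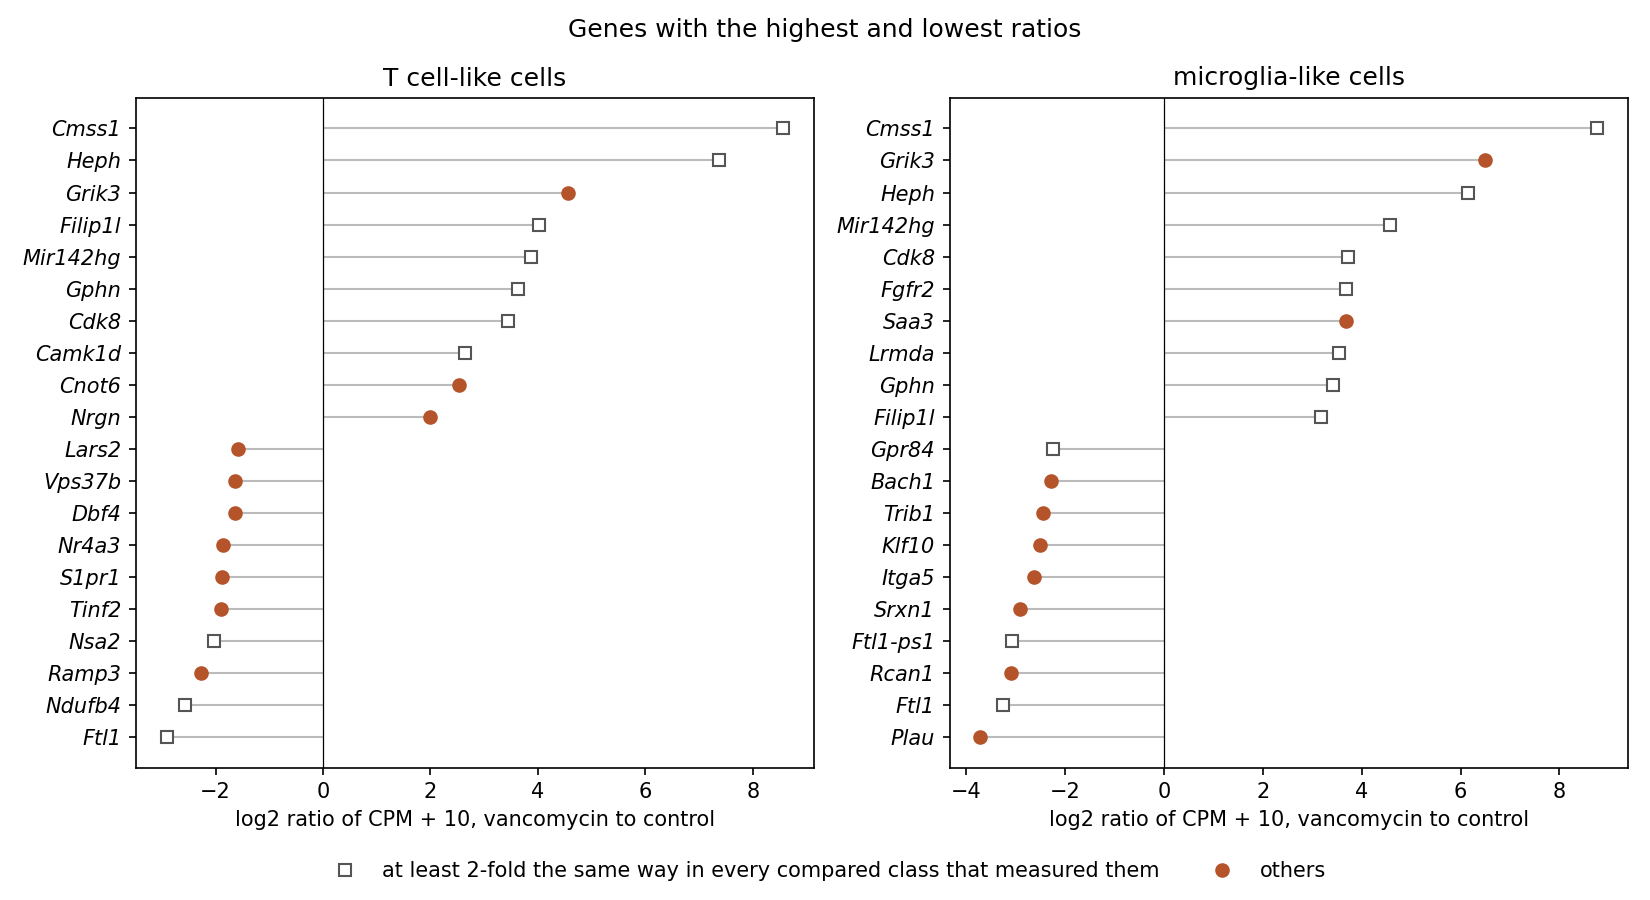
Log2 ratio of CPM + 10, vancomycin to control (x axis), for the 10 highest and 10 lowest genes in T cell-like (left) and microglia-like cells (right). Open squares mark genes at least 2-fold different in the same direction in every compared class that measured them (10 of 20 in T cell-like and 11 of 20 in microglia-like cells), filled circles the others; Heph and Grik3 in T cell-like cells and Grik3 in microglia-like cells had 0 control UMIs, so their points depend on the added 10 CPM.

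Across 9274 genes measured in at least 5 of the 9 compared classes, 38 were at least 2-fold higher and 9 at least 2-fold lower in the vancomycin library in every class that measured them. The log2 ratio of Cmss1 ran from 8.21 in NK cell-like to 8.99 in plasma cell-like cells, and the 38 genes included myelin genes (Mbp, Mal and Mobp among them) and immunoglobulin variable genes. The 9 lower genes were Ftl1, its pseudogene Ftl1-ps1, Lmna, Nsa2, Xist, Gpr84, Ndufb4, Fam177a and Rpl10-ps3, all named here because the count is small. Gpr84 was measured in 5 classes, Ftl1-ps1 and Fam177a in 6 and the other lower genes in all 9. The control library was made with Cell Ranger 6.0.1 and the vancomycin library with 7.2.0, per the file headers, so software and group cannot be told apart.

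Microglia-like cells of the vancomycin library had more RNA of antigen presentation and interferon-response genes and less of inflammatory cytokine and homeostatic genes. Cluster 6 held 475 vancomycin and 153 control cells, and cluster 0 held 411 and 576, so these levels move with the mix of clusters. H2-Ab1, an MHC class II chain gene, stood at 5759 against 1361 CPM (ratio interval 4.14 to 4.33), and Cd74, the class II invariant chain, at 28719 against 10818 CPM. Outside antigen-presenting classes, class II list medians ran from 0.19 in fibroblast-like to 2.76 in NK cell-like cells. Isg15, an interferon-induced ubiquitin-like protein gene, stood at 439.8 against 141 CPM (interval 2.90 to 3.35). Il1a, which encodes interleukin 1 alpha, stood at 871 against 2283 CPM (interval 0.371 to 0.392), and Ccl4 at 1874 against 4059.7 CPM (0.453 to 0.471). Ccl5 stood at 2891 against 363 CPM (ratio 7.97, 7.65 to 8.31).

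All 3 lists of interferon response and presentation lay at percentile 100 of the random lists. Of 25 type I interferon genes 12 were at least 2-fold higher and 0 lower (median 0.87), with Ifitm3 at 1.45, Rtp4 at 1.54 and Ifi27l2a at 0.82. Of 26 interferon gamma and MHC class I genes 10 were at least 2-fold higher and 0 lower (median 0.90), with Iigp1 at 2.17, Socs1 at 1.999, B2m at 0.54 and H2-D1 at 0.42. Of 11 MHC class II genes 7 were at least 2-fold higher and 0 lower (median 1.11), with H2-Eb1 at 1.75 and Ctss at 0.11, the last with the opposite sign after thinning, with cells weighted equally or less the other classes' median (-0.21). NF-kappaB and inflammatory cytokine genes lay at percentile 0.0, with 10 of 23 at least 2-fold lower and 0 higher (median -0.80). Ccl3 had a log2 ratio of -1.81 and Cxcl2, a neutrophil-drawing chemokine, of -1.78.

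Of the 18 homeostatic microglia genes 16 were lower with an interval below 1, 2 of them at least 2-fold, and none was at least 2-fold higher (median -0.57, percentile 0.36). Cst3 stood at 19756 against 32173 CPM, Fcrls had a log2 ratio of -1.72 and Gpr84, a fatty acid receptor gene, of -2.25. Gpr84 is a member by the fixed list only, and is among the 9 genes at least 2-fold lower in every class that measured them. Its fall is therefore not read as particular to microglia-like cells or to a homeostatic state. Disease-associated genes went both ways (median -0.01, mean 0.18, percentile 67.18; 3 of 21 at least 2-fold higher, 1 lower): Apoe, a lipid carrier, stood at 9786 against 4596 CPM and Cst7 at 270.3 against 58.0 CPM, while Csf1 stood at 41.2 against 198 CPM and Ctsd had a log2 ratio of -0.02. The chemokine list was split as well (median 0.30, percentile 98.42; 4 of 12 at least 2-fold higher, 3 lower), with Cxcl13, a B cell chemokine, at 1.45 (-0.15 less the other classes' median) and Ccl8 at 2.20. It shares Ccl2, Ccl3, Ccl4 and Cxcl10 with the NF-kappaB list.

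Tgfb1 had a log2 ratio of -1.64 in microglia-like cells (ratio interval 0.297 to 0.328). In the TGF-beta list 3 of 23 members were at least 2-fold lower and 0 higher (median -0.16, percentile 9.53), with Skil at -1.31, Tgfbr1 at -0.51 and Tgfbr2 at -0.35. The T cell to microglia axis list had a median of -0.13 and a mean of 0.12 (percentile 11.61; 2 of 14 at least 2-fold higher, 2 lower). The microbial metabolite sensing list had a median of 0.21 but a mean of -0.14 (percentile 97.54; 0 of 13 at least 2-fold higher, 2 lower), and a median of 0.43 with a pseudocount of 1 CPM. Cd14, the co-receptor for bacterial lipopolysaccharide, stood at 947 against 3251 CPM, and Tlr2, a receptor for bacterial lipoproteins, at 199.9 against 459 CPM. Nf1 stood at 74.0 against 42.5 CPM (ratio 1.74, 1.51 to 2.004). The log2 ratios of Tlr2 (0.35), Nf1 (-0.18) and Skil (0.09) turned sign in this class less the other classes' median.

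Several lists of basic metabolism also lay outside the central 95% in microglia-like cells. Oxidative phosphorylation had a median of 0.35, 0.23 after thinning (percentile 99.98; 0 of 26 at least 2-fold in either direction), with Cox4i1 at 0.53, Cox8a at 0.56 and Cox5a at 0.58. Ribosomal protein genes had a median of 0.40 (percentile 99.99; 0 of 28 in either direction), with Rps24 at 0.49, Rps20 at 0.80, Rpl10 at 0.66 and Rps29 at -0.49. Glycolysis and hypoxia genes had a median of 0.20 (percentile 97.56; 1 of 21 at least 2-fold higher, 1 lower), with Gapdh at 0.44, Aldoa at 0.13, Ddit4 at 1.36 and Pfkfb3 at -1.40. Proliferation genes had a median of 0.18 (percentile 98.19; 0 of 24 in either direction), 0.58 with a pseudocount of 1 CPM and 0.04 with 50 CPM, with Tubb5 at 0.34, Cdk1 at 0.48 (plain ratio 2.97, 1.72 to 5.40) and Hmgb2 at -0.01, and with Pclaf at 2.95 CPM against 0 UMIs in the control (ratio interval from 5.09). Cholesterol synthesis genes had a median of -0.18 (percentile 1.22; 0 of 19 in either direction), 0.01 after thinning, with Srebf2 at -0.81 (plain ratio 0.475), Cyp51 at -0.72, Msmo1 at -0.66 and Insig1 at -0.24. Blood-brain barrier genes had a median of -0.21 (percentile 0.77; 0 of 9 in either direction), with Slc2a1 at -0.65, Tjp1 at -0.63 and Slc7a5 at -0.85 (plain ratio 0.474). The log2 ratios of Cox4i1 (-0.04), Rps29 (0.0038), Pclaf (-0.10), Cyp51 (0.06) and Insig1 (0.70) turned sign less the other classes' median.

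As in T cell-like cells, all 17 myelin genes were higher with an interval above 1 (median 0.68, percentile 100), with Mbp at 839 against 55.1 CPM. Inside the central 95% lay the CD8 list (0.08), the CD4 and regulatory list (0.19), checkpoint genes (0.02), naive genes (-0.09), tissue-resident genes (0.21), homing (-0.13), immediate early genes (-0.09, mean 0.01), heat shock (-0.28), RAS-MAPK output (-0.12), reactive astrocyte genes (0.08) and mitochondrially encoded genes (-0.26). The sex-linked list had a median of 0.39 (percentile 98.46; mean -0.04). Of the genes of T cells fixed for naming, Cd8a (-0.04), Cd8b1 (-0.07), Cd4 (-0.08), Gzmk (-0.19), Pdcd1 (-0.06), Ifng (0.17) and Mdk (-0.22) had intervals that included 1, and Gzmb stood at 5.56 against 2.19 CPM, with a log2 ratio of 0.35 that was -0.09 with every cell weighted equally.

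Among named genes of microglia-like cells, Plau (ENSMUSG00000021822, chromosome 14, 20836660 to 20843385), the urokinase gene, had the lowest log2 ratio. It stood at 45.2 against 715 CPM (ratio 0.0632, 0.0569 to 0.0700). Ftl1 (-3.25), Rcan1, a calcineurin regulator (-3.11), Ftl1-ps1 (-3.07), Srxn1, which encodes sulfiredoxin (-2.92), Itga5, a fibronectin receptor chain (-2.63), Klf10 (-2.52), Trib1 (-2.45) and Bach1 (-2.30) followed. At the high end, Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), an acute phase protein gene, stood at 127 against 0.731 CPM (ratio 174, 74.2 to 536). Cmss1 (8.75), Mir142hg (4.58), Cdk8 (3.72), Lrmda (3.54), Gphn (3.42) and Filip1l (3.18) stood there too. Grik3 was at 886 CPM against 0 control UMIs, at least 2021-fold higher. Heph and Fgfr2 had 1 control UMI each, with ratio intervals of 867 to 190903 and 147 to 32496. Plau, Il1a and Gpr84 were also among the 10 leading genes of cluster 0, so their ratios move with the mix of microglia-like clusters. Of these 20 genes 11 were at least 2-fold different the same way in every class that measured them, and less the other classes' median 4 turned sign: Heph (-0.0034), Cdk8 (-0.16), Gphn (-0.12) and Filip1l (-0.32).

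**Figure D4:**
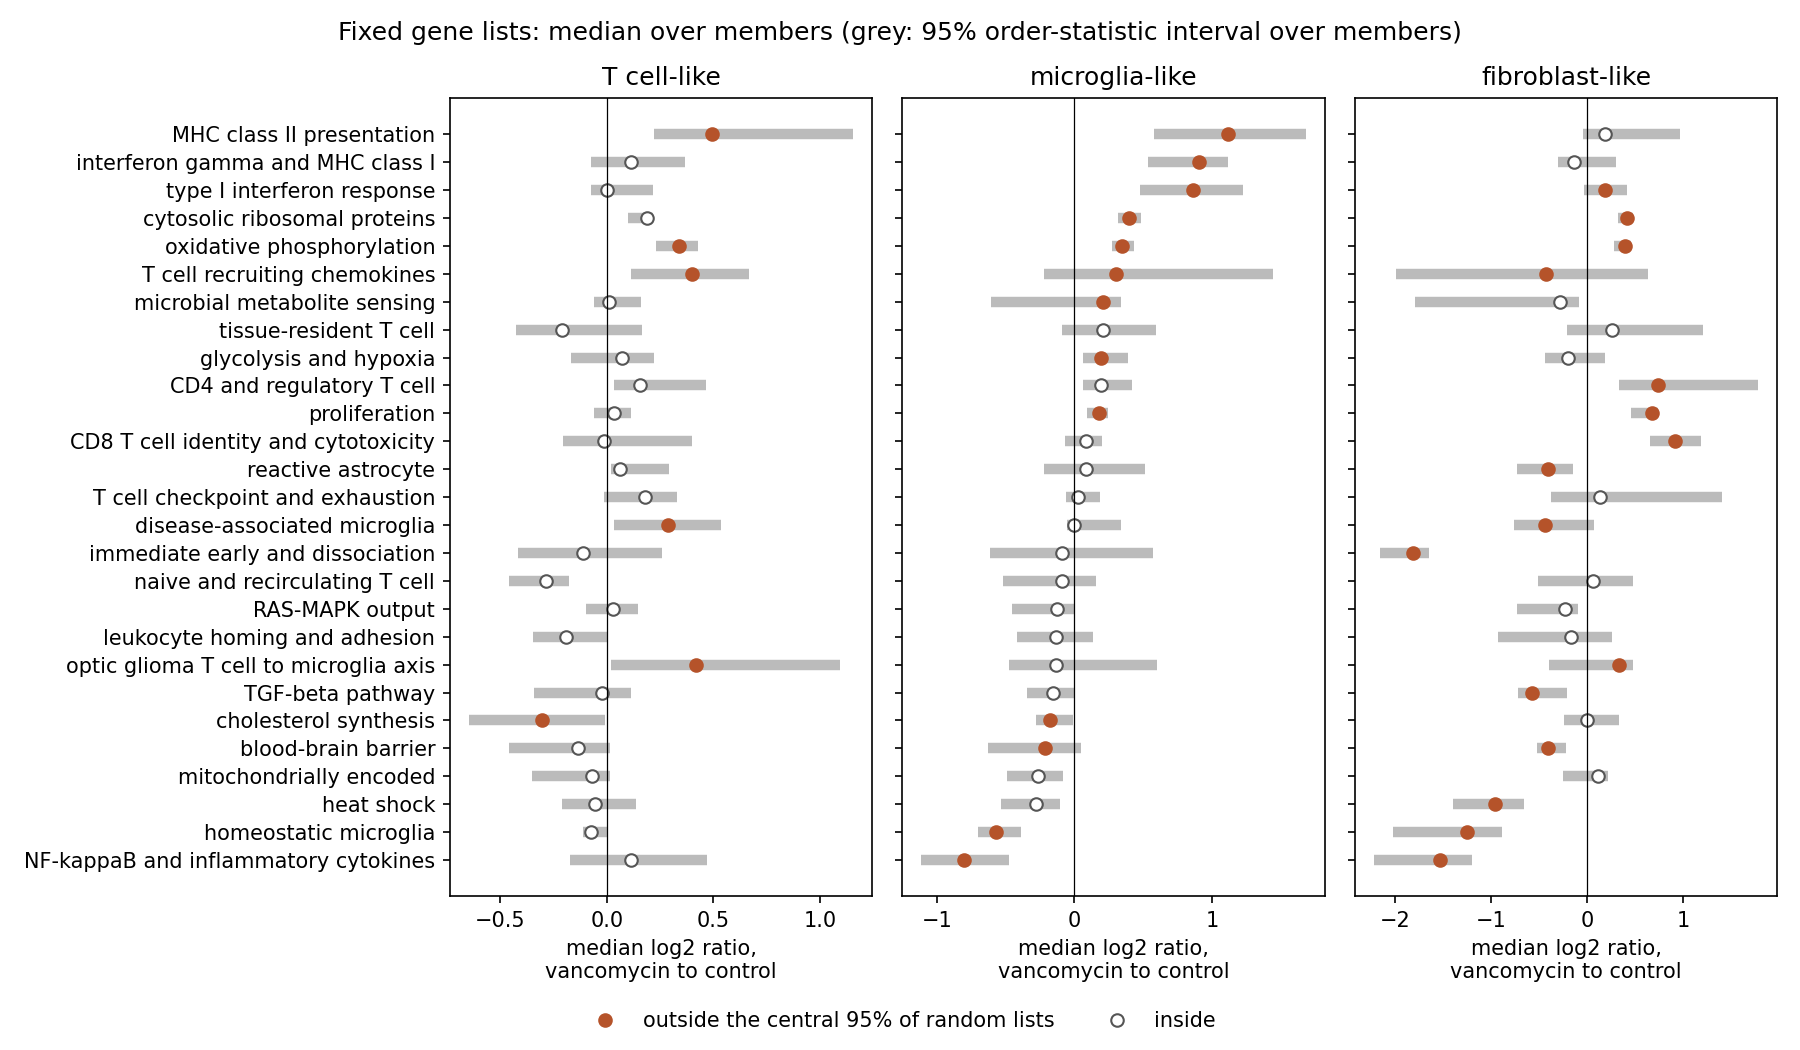
Median log2 ratio, vancomycin to control, over the measured members of each fixed list (x axis, with a scale of its own in each panel) in T cell-like, microglia-like and fibroblast-like cells. Grey bars are 95% order-statistic intervals over members, filled points lie outside the central 95% of 10000 matched random lists; in microglia-like cells MHC class II (1.11) is highest and NF-kappaB (-0.80) lowest.

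The fibroblast-like class of the vancomycin library held less RNA of stress, early response, inflammatory and microglia genes. All 18 immediate early genes were at least 2-fold lower (median -1.82, percentile 0.0): Fos stood at 1814 against 7084 CPM, Egr1 at 1081 against 5604 CPM, Atf3 at 64.8 against 960.3 CPM and Fosb at 217 against 1844 CPM. Of 23 NF-kappaB and cytokine genes 18 were at least 2-fold lower and 0 higher (median -1.53, percentile 0.0), with Cxcl1 at 57.2 against 603 CPM and Nfkbia at -0.64. Homeostatic microglia genes were lower in the same class (median -1.25, percentile 0.0; 11 of 17 at least 2-fold lower). Heat shock genes had a median of -0.96 (percentile 0.0; 6 of 13 at least 2-fold lower, 0 higher), with Dnajb1 at -3.21 and Hspa1a at -2.33. TGF-beta genes had a median of -0.57 (percentile 0.0; 5 of 25 at least 2-fold lower, 0 higher), with Skil at -1.55, Tgfbi at -0.72 and Tgfb1 at -1.16. Immediate early genes are also induced by tissue dissociation.

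Several lists of other cell types also lay outside the central 95% in fibroblast-like cells. The CD8 list had a median of 0.92 (percentile 100; 0.66 with 3 members at 0 set to 3 counts), the CD4 and regulatory list of 0.74 (percentile 100; 0.63 with 2 members so set) and myelin of 2.18 (percentile 100; 2.02 with 8 members so set). The chemokine list had a median of -0.43 (percentile 0.93), with Ccl2 at -2.87 and Cxcl12 at -0.56, the axis list of 0.33 (percentile 99.18, mean -0.10), disease-associated microglia of -0.44 (percentile 0.20) and reactive astrocyte genes of -0.41 (percentile 0.54). Type I interferon genes had a median of 0.19 (percentile 98.07), oxidative phosphorylation of 0.39 (percentile 99.93), ribosomal proteins of 0.42 (percentile 99.94), the blood-brain barrier of -0.41 (percentile 1.23) and proliferation of 0.67 (percentile 100; 0.32 with 9 members so set).

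The highest ratios in fibroblast-like cells were those of Cmss1 (8.40), Slpi, a protease inhibitor gene (975 CPM against 0 UMIs, at least 273-fold higher), Grik3 (at least 134-fold), Klk6 (at least 29.1-fold), Chgb (at least 28.6-fold), Heph (5.32), Aplp1 (3.79), Tubb4a (3.57) and Gphn (3.45). Klk6, Aplp1 and Tubb4a are among the leading genes of oligodendrocyte-like clusters with 0 control cells. Chga, which encodes the granule protein chromogranin A, stood at 600.5 CPM against 2 control UMIs, with a ratio interval of 69.7 to 2085. Chga and Chgb lead the unnamed cluster of 345 vancomycin and 25 control cells. The lowest were Cd14 (-3.93), Atf3, Ftl1 (-3.58), Ccl3 (-3.36), C3ar1 (-3.27), Dnajb1 and Cxcl1 (-3.19), with 2 vancomycin UMIs of Plau (ratio interval 0.000695 to 0.0215), 3 of Fam177a (0.00203 to 0.0301) and 2 of Gpr84 (0.000926 to 0.0289). Less the other classes' median, the log2 ratios of Cmss1 (-0.25), Gphn (-0.08) and Heph (-1.06) turned negative in this class.

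In the 6 other compared classes Cmss1 was highest, with log2 ratios of 8.99 in plasma cell-like, 8.94 in border-associated macrophage-like, 8.79 in astrocyte-like, 8.55 in dendritic cell-like, 8.22 in oligodendrocyte precursor-like and 8.21 in NK cell-like cells. Heph had 0 control UMIs and was at least 432-fold higher in plasma cell-like, 476-fold in dendritic cell-like, 355-fold in NK cell-like, 215-fold in border-associated macrophage-like and 48.8-fold in oligodendrocyte precursor-like cells, where Filip1l was at least 48.6-fold higher. Grik3, also at 0 in the control, was at least 249-fold higher in plasma cell-like, 160-fold in dendritic cell-like, 59.1-fold in NK cell-like and 254-fold in border-associated macrophage-like cells. Astrocyte-like cells had 1 control UMI each of Apod (ratio interval 93.4 to 20610) and Chga (81.2 to 17942), among the leading genes of oligodendrocyte-like clusters and the unnamed cluster. At the low end stood Ftl1 (-2.87), Lars2 (-2.01) and Nsa2 (-1.69) in plasma cell-like, and Ftl1 (-3.21), Ndufb4 (-2.57) and Nsa2 (-2.38) in NK cell-like cells. Lowest in border-associated macrophage-like cells were Ftl1-ps1 (-3.26), Ftl1 (-3.22) and Thbs1 (-2.97), and in dendritic cell-like cells Fam177a (-4.85), Ftl1 (-3.62) and Il12b, the interleukin 12 subunit (-3.25). Il12b led cluster 18, which held 67 of 1355 vancomycin and 45 of 120 control dendritic cell-like cells, so its ratio moves with the mix of clusters. Socs3 (-3.69), Maff (-3.63) and Ccn1 (-3.52) were lowest in astrocyte-like cells, and Hist1h2ap (-4.26), Fosb (-3.57) and Klf4 (-3.44) in oligodendrocyte precursor-like cells.

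Among these 6 classes, immediate early genes had a median of -2.12 in astrocyte-like and -2.04 in oligodendrocyte precursor-like cells, with 17 of 18 at least 2-fold lower in each, against 0.37 in NK cell-like cells (percentile 99.89). In oligodendrocyte precursor-like cells (52 control cells) 8 of 19 RAS-MAPK output genes were at least 2-fold lower and 0 higher (median -0.70, percentile 0.0). That list shares Egr1 (-2.98 in this class) with the immediate early genes, and its fall was not told apart from theirs. Reactive astrocyte genes had a median of 1.23 in astrocyte-like cells (percentile 100; 10 of 19 at least 2-fold higher, 2 lower). NF-kappaB genes had medians of -0.46 in border-associated macrophage-like (percentile 0.67) and -0.69 in dendritic cell-like cells (percentile 0.01), and of 0.47 in NK cell-like cells (percentile 99.97), the last at -0.10 after thinning. Interferon gamma and MHC class I genes had a median of 0.54 in border-associated macrophage-like cells (percentile 100; 7 of 26 at least 2-fold higher, 0 lower). Myelin medians ran from 1.39 in border-associated macrophage-like to 2.79 in astrocyte-like cells, at percentile 100 in each. With members at 0 set to 3 counts those 2 medians were 0.89 and 2.15, that of NK cell-like cells 1.53 and that of oligodendrocyte precursor-like cells 1.60.

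Tgfb1 was lower with vancomycin in 8 of 9 classes (interval below 1), with free RNA and software untested as causes. Its log2 ratios included -0.94 in plasma cell-like, -2.02 in NK cell-like (342 against 1413 CPM), -1.28 in border-associated macrophage-like, -1.22 in dendritic cell-like and -1.08 in oligodendrocyte precursor-like cells. The last had 14 control UMIs and was 1.08 after thinning. Less the other classes' median, Tgfb1 turned positive in fibroblast-like (0.12), plasma cell-like (0.35), dendritic cell-like (0.06) and oligodendrocyte precursor-like cells (0.21), and Tgfbr2 in plasma cell-like cells (0.01). In astrocyte-like cells Tgfb1 was -0.34 (ratio interval 0.274 to 1.72). Tgfbr1 stood at -1.13 in fibroblast-like and -0.80 in border-associated macrophage-like cells, and its interval included 1 in plasma cell-like (0.16), NK cell-like (0.40), dendritic cell-like (0.28), astrocyte-like (-0.08) and oligodendrocyte precursor-like cells (0.52). Tgfbr2 was -0.58 in fibroblast-like, -0.34 in plasma cell-like and -0.59 in border-associated macrophage-like cells, with 3 control UMIs and a ratio interval of 1.15 to 19.9 in astrocyte-like cells, and its interval included 1 in NK cell-like (0.09), dendritic cell-like (-0.20) and oligodendrocyte precursor-like cells (-0.14).

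Ccl5 and Ccl4 differed by class. Ccl5 stood at 2.37 in border-associated macrophage-like, 1.38 in fibroblast-like, 0.47 in plasma cell-like, 4.23 in astrocyte-like and 1.95 in oligodendrocyte precursor-like cells, and at -1.96 in dendritic cell-like (809 against 3175 CPM) and -0.54 in NK cell-like cells. Ccl4 stood at 1.73 in plasma cell-like, 1.93 in NK cell-like and 1.24 in astrocyte-like cells, at -2.52 in fibroblast-like, -0.27 in border-associated macrophage-like and -0.44 in dendritic cell-like cells, and was at least 1.93-fold higher in oligodendrocyte precursor-like cells with 0 control UMIs. Nf1 was higher with an interval above 1 in plasma cell-like (0.41), border-associated macrophage-like (0.85), dendritic cell-like (1.11), astrocyte-like (1.01) and oligodendrocyte precursor-like cells (0.97), and its interval included 1 in fibroblast-like (0.37) and NK cell-like cells (0.36). Nf1 has 226070 intronic bases, so intron reads, if counted in the vancomycin library alone, could raise it. Mdk stood at 0.36 in fibroblast-like, 0.34 in astrocyte-like and 0.57 in oligodendrocyte precursor-like cells, and its interval included 1 in dendritic cell-like cells (-0.23). With 1 and 2 control UMIs its ratio intervals were 0.209 to 66.1 in border-associated macrophage-like and 0.309 to 11.0 in plasma cell-like cells. The log2 ratios of Ccl5 (-1.19) and Nf1 (-0.44) in plasma cell-like and of Mdk (-0.01) in astrocyte-like cells turned negative less the other classes' median.

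Genes of cytotoxic lymphocytes were measured outside T cells too, where free RNA and doublets can carry them. In NK cell-like cells Ifng stood at 203 against 38.0 CPM (ratio interval 3.52 to 8.44), Gzmb at -0.80 and Cd8b1 at -1.12, with intervals that included 1 for Cd8a (0.32), Gzmk (0.19) and Pdcd1 (-0.45). Plasma cell-like cells had Ifng at -1.05, Gzmb at -0.53, Gzmk at -0.96, Pdcd1 at -0.60, Cd8a at -1.07, Cd8b1 at -0.90 and Cd4 at -0.72. Fibroblast-like cells had Cd8a at 1.19 and Cd8b1 at 0.67, Gzmk with an interval that included 1 (0.10), Ifng at least 2.45-fold and Gzmb at least 2.67-fold higher against 0 control UMIs, and ratio intervals of 3.82 to 56.5 for Pdcd1 (3 control UMIs) and 1.19 to 303 for Cd4 (1 control UMI). Border-associated macrophage-like cells had Cd4 at -0.67, intervals that included 1 for Cd8a (-0.07) and Cd8b1 (0.12), and with 3 and 1 control UMIs ratio intervals of 0.921 to 14.3 for Pdcd1 and 0.506 to 132 for Gzmk. In dendritic cell-like cells Gzmb stood at -0.71, Cd8b1 was at least 5.05-fold higher against 0 UMIs, Cd8a and Ifng had 3 control UMIs each (2.29 to 32.9 and 0.546 to 8.23), and the interval included 1 for Pdcd1 (-0.10), Gzmk (-0.06) and Cd4 (-0.41).

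In astrocyte-like cells Pdcd1 was at least 5.37-fold and Gzmb at least 3.98-fold higher against 0 control UMIs, and Cd8a, Cd8b1, Ifng and Gzmk had 1 or 2 control UMIs, with ratio intervals of 1.76 to 60.9, 1.20 to 328, 0.624 to 26.5 and 0.739 to 226. With every cell weighted equally, the log2 ratios of Ccl4 (-0.85) and Cd8a (-0.49) turned negative in this class, as did that of Cd8b1 after thinning (-1.13). In oligodendrocyte precursor-like cells Cd8b1 was at least 1.62-fold and Cd8a at least 1.39-fold higher against 0 UMIs, Pdcd1 and Cd4 had 2 control UMIs each (0.583 to 18.4 and 0.175 to 6.19), and Gzmk and Gzmb had 22 and 15 vancomycin UMIs against 0, levels of 2.76 and 1.88 CPM that lay below the 6.11 CPM of 3 control counts, so no fold is given.

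Cells with the most cell cycle RNA had formed the cycling cluster, where 222 of 224 vancomycin and 63 of 63 control cells had at least 2 UMIs over 8 cell cycle genes. The shares below therefore count only cells that stayed in the other classes. With at least 2 UMIs over 8 cell cycle genes at 1000 UMIs per cell, 0.341% of T cell-like cells were proliferating with vancomycin (12 of 3518, 0.176 to 0.595) and 0.509% in the control (9 of 1767, 0.233 to 0.965). The unthinned shares were 5.02% (4.33 to 5.79) and 5.20% (4.25 to 6.31). Among microglia-like cells the shares were 0.2498% (3 of 1201) and 0.0978% (1 of 1022), and unthinned 1.18% (0.691 to 1.89) and 0.495% (0.182 to 1.07). With at least 1 UMI after thinning, the shares were 4.97% and 4.81% of T cell-like and 2.08% and 1.17% of microglia-like cells. With at least 1 UMI unthinned, they were 16.8% (15.6 to 18.0) and 18.5% (16.8 to 20.3) of T cell-like and 8.36% (6.98 to 9.91) and 3.63% (2.65 to 4.84) of microglia-like cells, the last a difference beyond the intervals that was not detectable after thinning.

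Summed over all kept cells, the libraries differed in the sex makeup of their pools and in the cells they held. Xist, the RNA of the inactive X chromosome in females, stood at 91.4 CPM with vancomycin and 386.5 CPM in the control (ratio 0.236, 0.230 to 0.243). Of the Y-linked genes, Eif2s3y stood at 47.0 against 19.9 CPM, Ddx3y at 42.9 against 23.9 CPM and Uty at 18.9 against 6.25 CPM. Mbp stood at 2737 against 79.1 CPM and the haemoglobin gene Hbb-bs at 4833 against 642 CPM. The T cell gene Cd3e stood at 229.8 against 666 CPM, the microglia gene P2ry12 at 58.6 against 311 CPM, Tgfb1 at 91.5 against 569.9 CPM and Nf1 at 39.9 against 21.5 CPM.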

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

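The tests of counted introns, of broken oligodendrocytes and of handling in this part were chosen only after the results they measure were seen, while those of free RNA, overlapping genes, depth and intron dilution were written down before their results, the last with a matching of random lists that was added after the data were seen. The groups, gene lists and most alternative settings were set before the data were examined, and set after it were the rule that left hormone-led clusters unnamed and the narrowing of the list members named.

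The first pattern is the 38 genes at least 2-fold higher and the 9 genes at least 2-fold lower in the vancomycin library in every compared class that measured them, at least 5 of the 9. The 38 had a median intronic length of 46230 bases against 10780 in random sets (percentile 100), which is consistent with reads in introns counted in that library alone, though the tenth of genes with the longest introns had median log2 ratios of 0.19 in T cell-like and 0.13 in microglia-like cells against 0.09 and 0.16 for the shortest. Free RNA may carry part of it: for 19 of the 38 (50%, the bound set beforehand) the gain in T cell-like cells was over 5 times that of free RNA, with Cmss1, Heph, Gphn and Cdk8 over it and Mbp and the immunoglobulin genes not. Loss of reads to overlapping genes of the same strand is argued against for the 9 lower genes, of which 0 overlapped another (percentile 30.82 of random sets). The Cell Ranger version goes with the group, and vancomycin itself stays untested.

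The second pattern is the lack of oligodendrocyte-like cells in the control library, against 25.7% with vancomycin. Lower depth is argued against, since 3.637% of the vancomycin oligodendrocyte-like cells would fall under 500 UMIs when scaled by 0.719, the ratio of the median UMIs. Breakage of oligodendrocytes after dissociation is argued against as well, since myelin gene CPM in control T cell-like cells was 8.389% (7.90 to 8.90) of that in vancomycin T cell-like cells, 120.3 against 1434 CPM. A difference in myelin removal or in the tissue taken stays open and could not be tested with 1 library per group, and so does vancomycin.

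The third pattern is the lower immediate early RNA in 3 classes of the vancomycin library, with medians of -2.12 in astrocyte-like, -2.04 in oligodendrocyte precursor-like and -1.82 in fibroblast-like cells. A difference in handling that acts on all cells may add to it but stays undecided: the median was below 0 in 7 of the 9 compared classes, inside the central 95% of random lists in 4 of these (-0.11 in T cell-like and -0.09 in microglia-like cells), and above 0 in 2, with 0.37 in NK cell-like cells (percentile 99.89). Fos stood at 3823 against 1145 CPM in microglia-like cells. Dilution by counted introns is argued against, since the list stayed below the 2.5th percentile of random lists matched on intronic length in 3 of 3 classes. The treatment stays open and untested.

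The unnamed cluster led by hormone genes held 2.27% of vancomycin cells, in cells that no comparison used. For 13 lists the medians of 2 classes lay on opposite sides of 0 and each outside the central 95% of random lists, and these differences between classes were not tested. The CD4 and regulatory list stood at -0.71 in dendritic cell-like and 0.74 in fibroblast-like cells (0.63 with members at 0 set to 3 counts). The CD8 list stood at -0.18 in plasma cell-like and 1.17 in astrocyte-like cells (1.05 so set), and chemokines at -0.59 in dendritic cell-like and 1.10 in plasma cell-like cells (1.02 so set). NF-kappaB genes ran from -1.53 in fibroblast-like to 0.47 in NK cell-like cells (-0.10 after thinning), immediate early genes from -2.12 in astrocyte-like to 0.37 in NK cell-like cells, and reactive astrocyte genes from -0.41 in fibroblast-like to 1.23 in astrocyte-like cells. Homeostatic microglia genes stood at -1.25 in fibroblast-like and 0.46 in oligodendrocyte precursor-like cells (0.17 so set), and disease-associated genes at -0.44 in fibroblast-like and 0.71 in plasma cell-like cells. Cholesterol synthesis stood at -0.58 in oligodendrocyte precursor-like and 0.32 in astrocyte-like cells, and glycolysis and hypoxia at -0.28 in astrocyte-like and 0.29 in border-associated macrophage-like cells. Microbial metabolite sensing ran from -0.26 in dendritic cell-like to 0.21 in microglia-like cells, and the T cell to microglia axis from -0.44 in dendritic cell-like to 0.42 in T cell-like cells. Type I interferon genes stood at -0.24 in oligodendrocyte precursor-like (-0.32 so set, 0.05 with doublets kept) and 0.87 in microglia-like cells.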

How the results depend on the processing

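The settings listed above as added after the data were seen, and which lists count as answering a comparison, were chosen then. No paired analysis was possible because each group has 1 library. Over all alternatives, 1849 of 3177 gene values stayed within their counting interval, 1257 lay outside it (1101 closer to 0 and 156 farther) and 71 turned sign. Of 2808 list values 2541 stayed within the interval of the main median, 258 lay outside it (95 closer to 0 and 163 farther) and 9 turned sign, and of 401 shares 286 stayed within their interval and 115 lay outside it (81 higher and 34 lower). No vancomycin innate lymphoid cell-like class formed with each library clustered alone, and no vancomycin pericyte-like class with doublets kept or at resolution 0.5, so these gave no value. Classes with few control cells limit the depth most, with 52 control oligodendrocyte precursor-like and 100 control astrocyte-like cells. The values below are those that turned sign and those outside the interval for results that answer a comparison, with the main value of shares and lists in parentheses, and the cause was not tested.

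With 1 doublet threshold for both libraries the vancomycin shares were 3.61% for border-associated macrophage-like cells (4.17%), 6.35% for microglia-like cells (9.44%), 6.74% for oligodendrocyte precursor-like cells (7.69%) and 6.29% for plasma cell-like cells (6.82%). The control share was 24.3% for microglia-like cells (29.5%). With DESeq2 size factors the list median was -0.054 for disease-associated microglia in microglia-like cells (-0.0052). With T cells taken as cells with at least 2 UMIs of T cell receptor and CD3 genes the control share was 49.3% for T cell-like cells (45.8%). The vancomycin share was 28.3% for T cell-like cells (23.4%). After thinning to 1000 UMIs that rule gave 44.1% for T cell-like cells (45.8%) in the control.

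With at least 1 UMI of a cell cycle gene the control shares were 4.81% for proliferating T cell-like cells (0.509%) and 1.17% for proliferating microglia-like cells (0.0978%). The vancomycin shares of these were 4.97% (0.341%) and 2.08% (0.2498%). With doublets kept the control share was 3.63% for NK cell-like cells (2.99%). The vancomycin shares were 22.6% for T cell-like cells (23.4%), 3.61% for border-associated macrophage-like cells (4.17%), 1.05% for endothelial cell-like cells (0.691%), 27.1% for oligodendrocyte-like cells (25.7%) and 6.14% for plasma cell-like cells (6.82%). Lists stood at 0.049 for type I interferon response in oligodendrocyte precursor-like cells (-0.24). With each library clustered alone the vancomycin shares were 1.22% for NK cell-like cells (1.01%), 8.40% for dendritic cell-like cells (8.91%), 2.35% for fibroblast-like cells (2.02%), 10.0% for microglia-like cells (9.44%) and 6.17% for plasma cell-like cells (6.82%). The control shares were 3.09% for astrocyte-like cells (2.43%), 4.11% for border-associated macrophage-like cells (2.99%), 1.10% for dendritic cell-like cells (2.92%), 2.12% for innate lymphoid cell-like cells (1.31%) and 0.438% for neutrophil-like cells (0.949%). With every cell weighted equally the log2 ratios in astrocyte-like cells turned to -0.85 for Ccl4 and -0.49 for Cd8a. They turned to -0.094 for Cd8a in T cell-like cells and to -0.18 for Ctss and -0.093 for Gzmb in microglia-like cells. Lists stood at 0.20 for MHC class II presentation in T cell-like cells (0.49), -0.16 for disease-associated microglia in microglia-like cells (-0.0052), -0.018 for interferon gamma and MHC class I in plasma cell-like cells (0.45) and 0.26 for oxidative phosphorylation in microglia-like cells (0.35).

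With members of at least 50 UMIs the list median was -0.37 for T cell checkpoint and exhaustion in astrocyte-like cells (0.78). Less the median of the other classes the log2 ratios in T cell-like cells turned to -0.13 for Atp5e, 0.56 for Bhlhe40, -0.43 for Camk1d, -1.26 for Ccl5, 0.15 for Cd4, -0.013 for Cd69, -0.057 for Cd74, -0.23 for Cd8a, -0.45 for Cdk8, -0.090 for Cmss1, -0.023 for Cox8a, -0.023 for Ctss, 0.32 for Ftl1, -0.68 for Grik3, -0.61 for H2-Ab1, -0.25 for H2-Eb1, 0.53 for Il7r, -0.78 for Mbp, -0.25 for Nf1 and -0.27 for Nkg7. In plasma cell-like cells the log2 ratio of genes turned to -1.19 for Ccl5, 0.36 for Ftl1, -0.28 for Grik3, -0.72 for Heph, -0.44 for Nf1, 0.15 for Nsa2, 0.35 for Tgfb1 and 0.012 for Tgfbr2. In fibroblast-like cells the log2 ratio of genes turned to -0.35 for Cd74, -0.25 for Cmss1, -0.076 for Gphn, -1.06 for Heph, -0.011 for Rpl10, 0.12 for Tgfb1 and 0.058 for Vim. In microglia-like cells the log2 ratio of genes turned to -0.16 for Cdk8, -0.035 for Cox4i1, -0.21 for Ctss, -0.15 for Cxcl13, 0.058 for Cyp51, -0.32 for Filip1l, -0.12 for Gphn, -0.0034 for Heph, 0.70 for Insig1, -0.18 for Nf1, -0.10 for Pclaf, 0.0038 for Rps29, 0.091 for Skil and 0.35 for Tlr2. In NK cell-like cells the log2 ratios turned to -0.45 for Cmss1, 0.024 for Ftl1 and -0.49 for Grik3. In dendritic cell-like cells the log2 ratios turned to -0.11 for Cmss1 and 0.064 for Tgfb1. In oligodendrocyte precursor-like cells the log2 ratios turned to -0.44 for Cmss1, -1.44 for Heph and 0.21 for Tgfb1. Ftl1 turned to 0.013 in border-associated macrophage-like cells and Mdk to -0.014 in astrocyte-like cells. Without a filter on cells the control share was 43.9% for T cell-like cells (45.8%). The vancomycin shares were 22.1% for T cell-like cells (23.4%), 8.29% for dendritic cell-like cells (8.91%), 4.47% for erythroid cell-like cells (1.08%), 6.47% for oligodendrocyte precursor-like cells (7.69%) and 24.5% for oligodendrocyte-like cells (25.7%). Without a filter on low counts the list medians were 0.013 for blood-brain barrier in plasma cell-like cells (-0.075) and 0.019 for reactive astrocyte in dendritic cell-like cells (-0.16).

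At a pseudocount of 1 CPM the list medians were 0.77 for T cell recruiting chemokines in T cell-like cells (0.40), 0.43 for microbial metabolite sensing in microglia-like cells (0.21) and 0.58 for proliferation in microglia-like cells (0.18). At a pseudocount of 50 CPM the list medians were 0.20 for MHC class II presentation in T cell-like cells (0.49), 0.097 for T cell recruiting chemokines in T cell-like cells (0.40), -0.17 for naive and recirculating T cell in T cell-like cells (-0.29), 0.27 for oxidative phosphorylation in microglia-like cells (0.35) and 0.039 for proliferation in microglia-like cells (0.18). At resolution 0.5 the vancomycin shares were 3.62% for border-associated macrophage-like cells (4.17%), 0.987% for endothelial cell-like cells (0.691%), 9.97% for microglia-like cells (9.44%), 6.57% for oligodendrocyte precursor-like cells (7.69%), 27.1% for oligodendrocyte-like cells (25.7%) and 6.35% for plasma cell-like cells (6.82%). At resolution 2.0 the vancomycin shares were 3.65% for border-associated macrophage-like cells (4.17%), 6.34% for microglia-like cells (9.44%) and 6.75% for oligodendrocyte precursor-like cells (7.69%). The control share was 24.4% for microglia-like cells (29.5%).

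As shares of the immune classes the vancomycin shares were 4.24% for B cell-like cells (2.43%), 1.75% for NK cell-like cells (1.01%), 40.8% for T cell-like cells (23.4%), 7.26% for border-associated macrophage-like cells (4.17%), 15.5% for dendritic cell-like cells (8.91%), 0.527% for innate lymphoid cell-like cells (0.303%), 16.5% for microglia-like cells (9.44%), 0.894% for neutrophil-like cells (0.513%), 11.9% for plasma cell-like cells (6.82%) and 0.630% for plasmacytoid dendritic cell-like cells (0.362%). The control shares were 50.6% for T cell-like cells (45.8%) and 32.6% for microglia-like cells (29.5%). As shares without oligodendrocyte-like cells the vancomycin shares were 3.27% for B cell-like cells (2.43%), 1.35% for NK cell-like cells (1.01%), 31.5% for T cell-like cells (23.4%), 1.88% for astrocyte-like cells (1.39%), 5.61% for border-associated macrophage-like cells (4.17%), 1.98% for cycling cells (1.47%), 12.0% for dendritic cell-like cells (8.91%), 0.929% for endothelial cell-like cells (0.691%), 1.45% for erythroid cell-like cells (1.08%), 2.72% for fibroblast-like cells (2.02%), 0.407% for innate lymphoid cell-like cells (0.303%), 12.7% for microglia-like cells (9.44%), 0.690% for neutrophil-like cells (0.513%), 10.3% for oligodendrocyte precursor-like cells (7.69%), 0.407% for pericyte-like cells (0.303%), 9.18% for plasma cell-like cells (6.82%) and 0.487% for plasmacytoid dendritic cell-like cells (0.362%). Under the stricter filter on cells the control shares were 3.79% for NK cell-like cells (2.99%), 48.3% for T cell-like cells (45.8%) and 27.2% for microglia-like cells (29.5%). The vancomycin shares were 1.29% for NK cell-like cells (1.01%), 24.7% for T cell-like cells (23.4%), 1.13% for astrocyte-like cells (1.39%), 1.85% for cycling cells (1.47%), 0.878% for erythroid cell-like cells (1.08%), 8.29% for microglia-like cells (9.44%) and 6.45% for oligodendrocyte precursor-like cells (7.69%). Thinned to 1000 UMIs the control shares were 17.3% for CD4 cells among T cell-like cells (31.8%) and 40.9% for CD8 cells among T cell-like cells (47.3%). The vancomycin shares were 15.2% for CD4 cells among T cell-like cells (33.3%) and 34.8% for CD8 cells among T cell-like cells (37.9%). The log2 ratios turned to -0.080 for Cd8a and 0.0082 for Tcf7 in T cell-like cells and -1.13 for Cd8b1 in astrocyte-like cells. They turned to 0.13 for Cst3 and 0.62 for Slc2a1 in fibroblast-like, -0.057 for Ctss in microglia-like and 1.08 for Tgfb1 in oligodendrocyte precursor-like cells. Lists stood at -0.098 for NF-kappaB and inflammatory cytokines in NK cell-like cells (0.47), 0.0056 for cholesterol synthesis in microglia-like cells (-0.18), 0.11 for cholesterol synthesis in plasma cell-like cells (-0.064), 0.31 for cytosolic ribosomal proteins in microglia-like cells (0.40), -0.13 for disease-associated microglia in microglia-like cells (-0.0052), -0.37 for leukocyte homing and adhesion in T cell-like cells (-0.19), 0.23 for oxidative phosphorylation in microglia-like cells (0.35) and -0.069 for sex-linked in dendritic cell-like cells (0.49).

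Without thinning, 5.20% of control T cell-like cells were proliferating (0.509%). The vancomycin shares were 5.02% of T cell-like (0.341%) and 1.18% of microglia-like cells (0.2498%).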

Other observations

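The test of pituitary cells in this part was chosen only after the unnamed cluster was seen, and its set of 4 genes was settled after the result of a larger set was seen.

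Dendritic cell-like cells of the vancomycin library had less RNA of homing and cholesterol genes. The homing and adhesion list had a median log2 ratio of -0.49 (percentile 0.0; 4 of 19 at least 2-fold lower, 0 higher) and cholesterol synthesis of -0.44 (percentile 0.05; 2 of 19 lower, 0 higher). Naive and recirculating T cell genes had a median of -0.46 (percentile 0.04; 4 of 11 lower, 1 higher). Cluster 18, with Il12b, Ccl22 and Ccr7 among its leading genes, held different shares of this class in the libraries, as given above. Plasma cell-like cells had a type I interferon median of 0.47 (percentile 99.96; 3 of 25 at least 2-fold higher, 0 lower), and NK cell-like cells had 0.42 (percentile 99.95; 4 of 22 higher, 0 lower). Ribosomal protein genes had medians of 0.46 in border-associated macrophage-like and 0.49 in oligodendrocyte precursor-like cells, at percentile 100 in both.

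The unnamed cluster held 345 vancomycin and 25 control cells, with median depths of 11811 and 2551 UMIs. In its vancomycin cells the granule gene Chga stood at 42340.0 CPM, the hormone subunit gene Cga at 19830.0 CPM, Pomc at 6737 CPM and Tshb at 5178 CPM, against 9.33, 11.2, 4.79 and 6.63 CPM in T cell-like cells. A hypothesis, which stays open, is that cells of the anterior pituitary, the gland that makes these hormones, may have entered the suspension. Thinned to 1000 UMIs, 50.93% of the cluster's vancomycin cells (164 of 322, 45.3 to 56.5, 23 left out) had a UMI of Pitx1, Pou1f1, Tbx19 or Nr5a1, transcription factor genes of that gland, against 0.227% of T cell-like cells (8 of 3518). Unthinned, the shares were 82.9% and 0.701%. These shares decide nothing, since Pitx1, at 873 CPM the most abundant of the 4 genes, was itself among the leading genes of the cluster, and the bound of 50% lies inside the interval. Of the other pituitary genes, Lhb stood at 340.4 CPM, Fshb at 202 CPM and Tbx19 at 19.4 CPM, each against 0 in T cell-like cells, while Gh stood at 0.981 CPM, Prl at 0.245 CPM and Pou1f1 at 0 CPM. The treatment was not tested as an explanation, and the labels name no such tissue.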
